A study of Mus musculus with 26 samples.

How the data were processed

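RNA was measured by sequencing in mouse testis. Per the labels, whole testes of C57BL/6 mice at postnatal day 21 came from wild-type mice, mice with a knockout of Nkapl, mice with a knockout of Sox30 and mice with an Nkapl allele called TGdel, and the series title also names a frameshift mutation of NKAPL. Each of the 3 testis sets has its own wild-type group, with 3 samples recorded per group. Pachytene spermatocytes and round spermatids were sorted from wild-type and Nkapl knockout mice, which makes 4 sorted groups with 2 libraries each. Per the labels' protocols, RNA was extracted with TRIzol and made into stranded total RNA libraries with a TruSeq kit.

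The deposited files hold raw read counts per gene for 24682 gene symbols, as whole numbers with no scaling. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq, DESeq2 and mm10 were used, without a statement of which step each one served. The annotation and the strand setting of the counting are not given in the sources used here, so overlapping genes, antisense genes and near-identical gene copies are uncertain. The files of sorted cells also hold HTSeq's summary lines of reads assigned to no gene, which were left out of library sizes and tests. Their share of all lines was 19.4% in wild-type spermatocytes, 23.3% in spermatocytes labelled knockout, 19.4% in wild-type spermatids and 24.5% in knockout spermatids.

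The 26 files hold 23 distinct libraries. In each testis set, a pair of the 6 files has identical values, and these were counted as 1 library, which leaves 5 libraries per set. In 15 of the 18 testis files, the column heading names another sample than the one the file is recorded under. Libraries are named here by their column heading. For 4 libraries the record and the heading name different groups: Nkapl wild type 3, Sox30 wild type 3, wild type 2 of the TGdel set and Nkapl TGdel 3. These 4 libraries were left out of the comparisons, and 19 libraries (11 of testis) that both sources put in the same group were used. The planned design had assumed 3 libraries against 3 in testis. It became 2 against 2 for the Nkapl knockout, 2 against 2 for the Sox30 knockout and 2 against 1 for TGdel. Grouping by the column heading and grouping by the file record were added as alternatives after the values had been seen. No label says whether the wild-type mice of the TGdel set are littermates of the mutants.

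Total counts per library ranged from 16469667 to 40010106. Genes were kept with edgeR's filterByExpr by group, and libraries were scaled by the trimmed mean of M-values. Each testis set was fitted alone, and the 8 sorted libraries were fitted together. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), two-sided, and every adjusted p of a gene given here comes from this test unless another tool is named. Standard errors are the log2 fold change divided by the square root of F. CPM, the counts scaled to a common library total, use edgeR's scaling factors in the comparisons of named genes and none for Nkapl, Sox30 and the epididymal panel in single libraries. Spread between libraries is given as SD.

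Curated gene lists, 24 in number and fixed before the data were examined, were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and again with a correlation estimated from the data. Adjusted p-values of lists cover the lists of 1 comparison. In the testis comparisons 2 further lists were used, holding genes with adjusted p under 0.05 and a log2 difference above 1 between the sorted spermatids and spermatocytes labelled wild type. These lists rest on spermatocyte labels that the Nkapl level goes against without settling them. Log2 fold changes by these labels correlated across genes at r = 0.75 with those in knockout spermatids, which runs the way of the labels. Lists with under 5 members tested were not given a set test. No list passes with an estimated correlation in any comparison (lowest adjusted p = 0.0649), which with 2 libraries per group rests on few degrees of freedom.

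The comparisons, tests, lists, thresholds, rule for named genes and most alternatives were chosen before the data were examined. The rule names Nkapl and Sox30 in every comparison. It then names the 6 largest rises and the 6 largest falls among genes that passed, had a mean log2 CPM of at least 1 and did not overlap between groups. It also names up to 2 called members with the smallest p of each called list, up to 2 members of the other lists, and the 5 genes with the smallest p in each difference of effects and overlap. Provisional gene symbols (Gm, Rik) were passed over. Genes outside the rule are given as chosen after their values were seen.

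The difference between 2 effects was tested as a contrast in a joint fit. Overlaps of calls were compared with the number expected for independent calls by a one-sided Fisher's exact test, and the comparisons overlapped share no libraries, except where the wild-type libraries of the Nkapl set serve as an alternative control for TGdel. A fold change against a group with 0 counts is given as a lower bound, against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with an exact 95% counting interval. Bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Coordinates come from the RefSeq annotation of GRCm38.p6, the assembly of mm10, in which 97.3% of the symbols in the files were found.

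The procedure was tested on simulated counts with 200 genes changed by known sizes. The simulation was first run after the first fit of the real counts. In the simulation of the Nkapl knockout testis comparison (16493 genes), 6.7% of calls were false, and 88.1% of genes changed by a log2 size of 1 were found. In that of the Sox30 knockout (17547 genes), 13.4% of calls were false and 52.2% were found. In that of TGdel (15973 genes), 20.9% were false and 71.6% were found. In those of spermatocytes labelled knockout (15374 genes), knockout spermatids (15382 genes) and wild-type spermatids against spermatocytes (15380 genes), 4.9%, 4.1% and 3% of calls were false. In those of the differences of effects, 9.7% of calls were false for Nkapl against Sox30 knockout (17552 genes), 10.2% for Nkapl knockout against TGdel (16950 genes) and 7.8% for spermatids against spermatocytes (15362 genes). In all testis comparisons and all differences of effects, the simulated calls at the 0.05 threshold therefore held more false calls than the threshold states.

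Alternatives were DESeq2 1.42.0, limma voom, DESeq2's size factors in edgeR, no filter beyond 1 count, libraries thinned to the smallest of their fit, each library left out in turn, the replicate number as a block, a log2 size of at least 1, all 11 testis libraries in 1 fit, only the 4 libraries compared in sorted cells and other wild-type controls for TGdel. R 4.3.3, Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.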

Results

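RNA sequencing counts describe whole mouse testis at postnatal day 21 and sorted germ cells. The testis libraries fall into 3 sets. The Nkapl set has 2 knockout and 2 wild-type libraries, the Sox30 set has 2 knockout and 2 wild-type libraries, and the TGdel set has 2 libraries of the Nkapl TGdel allele and 1 wild-type library. The sorted cells are pachytene spermatocytes, which are in the long prophase of meiosis, and round spermatids, which are the haploid cells that follow, with 2 libraries per cell type from wild-type and from Nkapl knockout mice. Total counts ranged from 20120729 to 25514132 in the Nkapl set, from 34794405 to 40010106 in the Sox30 set, from 16469667 to 17822056 in the TGdel set and from 18155299 to 19569272 in the sorted cells.

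Nkapl lies on chromosome 13 at 21467047 to 21468501 and Sox30 on chromosome 11 at 45979069 to 46017992 of GRCm38, both as protein-coding genes. Nkapl measured 73.9 and 77.6 CPM in the wild-type testes of the Nkapl set and 62.1 and 59.7 CPM in the knockout testes, a log2 fold change of -0.38 ± 0.06 (SE, adjusted p = 0.000143). In sorted round spermatids it fell from 79.3 ± 1.63 CPM (SD, n = 2) to 23.2 ± 0.664 CPM (n = 2), a log2 change of -1.89 ± 0.07 (adjusted p = 4.4e-20). In pachytene spermatocytes the values went against the labels: Nkapl was 98.6 ± 2.79 CPM in the libraries labelled wild type (n = 2) and 132 and 131 CPM in the libraries labelled knockout (log2 0.51 ± 0.05, adjusted p = 3.26e-09). Sox30 transcript was 78.2 and 84.0 CPM in Sox30-set wild-type testis and 46.2 and 60.3 CPM in Sox30 knockout testis, lower in both knockout libraries but short of the threshold (log2 -0.64 ± 0.17, adjusted p = 0.143). The labels do not say which part of either gene was removed, so counts outside a removed part would not show the deletion. In TGdel testis Nkapl measured 107.8 and 116.9 CPM against 100.7 CPM in the wild-type library, with a log2 change of 0.15 ± 0.12 (adjusted p = 0.769).

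**Figure D1:**
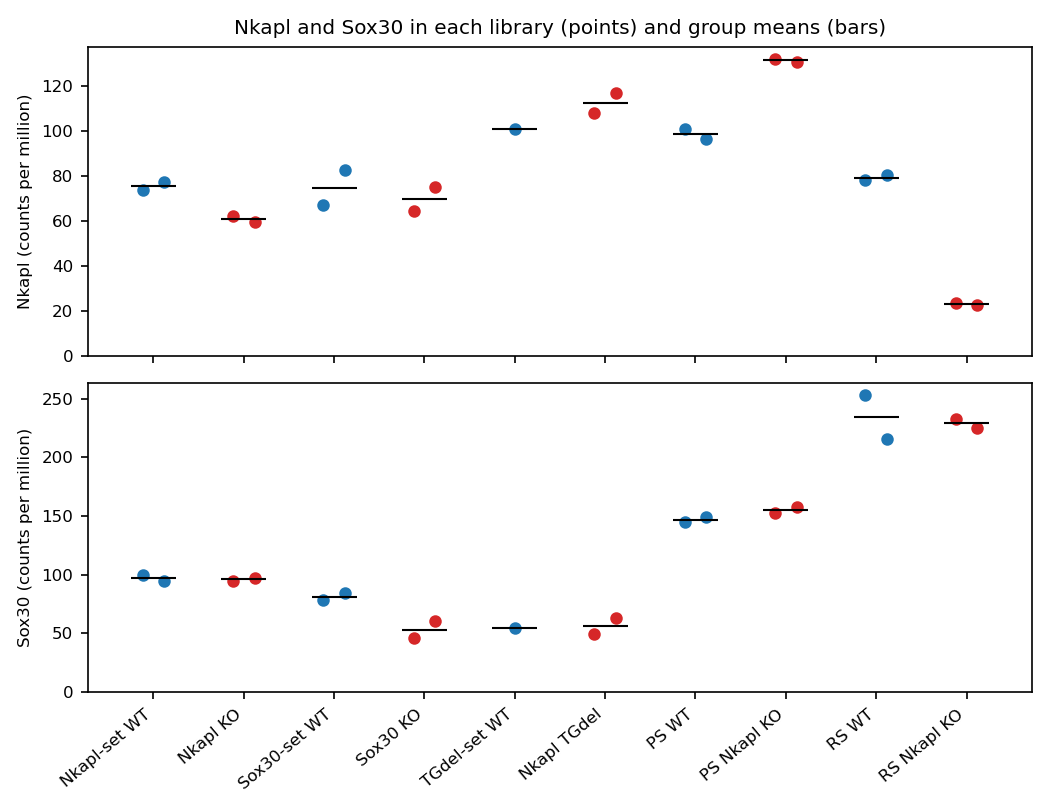
Library-scaled counts (CPM) of Nkapl and Sox30 in each library, by group. Points are libraries and bars are group means; Nkapl is lower than in wild type in both knockout round spermatid libraries (23.6 and 22.7 CPM) and higher in both libraries labelled knockout pachytene spermatocytes.

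The comparison of Nkapl knockout with wild-type testis asks which transcripts depend on this germ cell gene. It has n = 2 libraries against 2. Among the largest falls, Smcp, which encodes a protein of the sperm mitochondrial capsule, had 0 counts in both knockout libraries and 17.4 ± 5.52 CPM (SD) in wild type, at least 259.6-fold lower. Adam26a, the outer dense fibre gene Odf3, Galntl5, Spata45 and Tmco2 also had 0 counts and were at least 132-fold, 123-fold, 119.8-fold, 105-fold and 93.3-fold lower. Rises were smaller, led by Car3 (log2 1.95 ± 0.37), Mir1947 (1.88 ± 0.24), the enolase gene Eno2 (1.39 ± 0.26), Sfn (1.30 ± 0.28), H2-Q10 (1.30 ± 0.24) and the secreted Wnt inhibitor Dkk3 (1.11 ± 0.17). Car3 differed widely between the knockout libraries, at 3.94 ± 2.25 CPM. Of 16724 genes tested, 2117 rose and 3851 fell (edgeR quasi-likelihood, Benjamini-Hochberg), of which 34 and 1349 changed by a log2 size of at least 1. DESeq2 called 1090 higher, and a fit of all 11 testis libraries called 195 higher and 1688 lower. Without knockout library 2, 1210 genes rose. With libraries grouped by file record, which puts the library headed Nkapl wild type 3 among the knockouts, edgeR called 0 genes, with 415 at an unadjusted p under 0.05. The ribosomal RNA transcript Rn45s took 3.96% and 3.97% of counts in the wild-type libraries and 5.53% and 5.29% in the knockout libraries. In the library headed Nkapl wild type 3 it took 3.97%, which goes with the heading.

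Genes of the acrosome, the vesicle that sperm use to enter the egg, fell in 36 of 37 cases in Nkapl knockout testis and rose in 1 (the same counts adjusted over the list alone), with a median log2 fold change of -4.50, or -4.37 with genes at 0 counts set to their bound. The list ranked below other genes by camera (adjusted p = 2.43e-19, adjusted p = 0.334 with an estimated correlation). Within it, Zp3r fell by 7.17 ± 0.24 and Tmco5 fell by 7.62 ± 0.35 on the log2 scale. All 51 sperm tail and axoneme genes tested fell (51 adjusted over the list alone, median -0.64, adjusted p = 5.15e-26, and 0.233 with an estimated correlation), and the fibrous sheath genes Akap4 (-7.41 ± 0.31) and Akap3 (-3.40 ± 0.16) were among them. Of 22 genes for sperm ion transport 20 fell, the same adjusted over the list alone (adjusted p = 8.74e-11, and 0.313 with an estimated correlation), including the calcium channel genes Catsper1 (-7.39 ± 0.30) and Catsper4 (-6.35 ± 0.26). Of 20 germ cell glycolysis genes 15 fell and 2 rose, the same adjusted over the list alone (adjusted p = 5.26e-07, and 0.313 with an estimated correlation). Hexokinase Hk1 fell by 1.54 ± 0.06, and the sperm glycolysis enzyme Gapdhs had 1 count in knockout testis, a ratio of 1187 (95% counting interval 213 to 46928). Of 23 testis-specific kinases and phosphatases 17 fell and 0 rose (18 and 2 adjusted over the list alone, adjusted p = 5.26e-07, and 0.333 with an estimated correlation), with Tssk4 at -3.92 ± 0.22 and Tssk2 at -6.27 ± 0.40.

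Early meiotic prophase genes did not pass as a set in Nkapl knockout testis (9 of 38 rose and 6 fell, the same adjusted over the list alone, median 0.05, adjusted p = 0.193). Lists of later stages ranked lower. Of 29 pachytene spermatocyte genes 20 fell and 3 rose (21 and 3 adjusted over the list alone, median -0.31, adjusted p = 1.12e-06, and 0.24 with an estimated correlation), including Pgk2 (-1.39 ± 0.10) and the cyclin Ccna1 (-1.03 ± 0.07). Of 34 meiotic division genes 16 fell and 2 rose (17 and 2 adjusted over the list alone, adjusted p = 0.00576, and 0.333 with an estimated correlation), among them the kinase Plk1 (-1.02 ± 0.06) and the kinetochore motor Cenpe (-0.67 ± 0.05). Of 25 spermatid transcription regulators 15 fell and 1 rose (16 and 2 adjusted over the list alone, adjusted p = 2.35e-05, and 0.334 with an estimated correlation), including Zmynd15 (-1.53 ± 0.06) and Rfx1 (-1.16 ± 0.07). The list of protamine and spermatid chromatin genes did not pass as a set (7 of 14 fell and 4 rose, 8 and 4 adjusted over the list alone, adjusted p = 0.112), although Theg had 1 count in knockout testis, a ratio of 515 (92.0 to 20372), and the remodeller Chd5 fell by 2.41 ± 0.12. Among genes of the multicopy sex-linked list, Ssxb2 had 0 counts in knockout testis, and Ssxb1 and Ssxb2 are near-identical copies whose reads cannot be told apart.

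Sertoli cell markers, which belong to the somatic cells that nurse the germ cells, rose in 15 of 23 cases in Nkapl knockout testis and fell in 0 (16 and 1 adjusted over the list alone, median 0.26, adjusted p = 1.23e-06, and 0.357 with an estimated correlation), led by the stem cell factor gene Kitl (0.40 ± 0.05) and the junction gene Cldn11 (0.37 ± 0.05). Markers of differentiating spermatogonia rose in 7 of 14 cases (7 adjusted over the list alone, adjusted p = 0.00673, and 0.357 with an estimated correlation), including Kit (0.37 ± 0.06), whereas Dmrtb1 fell by 0.56 ± 0.05. Markers of undifferentiated spermatogonia also rose in 7 of 14 cases (7 adjusted over the list alone, adjusted p = 0.0154, and 0.357 with an estimated correlation), including Sall4 (0.47 ± 0.09) and Zbtb16 (0.37 ± 0.07). Neither spermatogonial list passed without wild-type library 2 (adjusted p = 0.0588 and 0.0696). By the sorted cells labelled wild type in the same series, with the doubt about the spermatocyte labels, 1303 of 2422 spermatid-enriched genes fell and 116 rose (1332 and 141 adjusted over the list alone, adjusted p = 2.69e-18, and 0.334 with an estimated correlation), with Zan, a sperm surface protein gene, at -5.89 ± 0.12. Of 2858 spermatocyte-enriched genes 815 rose and 82 fell (778 and 78 adjusted over the list alone, adjusted p = 2.35e-16, and 0.233 with an estimated correlation), led by Lmln (0.75 ± 0.06) and Col18a1 (0.57 ± 0.05).

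Sox30 is a transcription factor of meiotic and early haploid germ cells, and the comparison of its knockout with wild-type testis asks which transcripts need it (n = 2 libraries against 2). Iqcf3, Odf3, the acrosome gene Spaca7, the spermatid linker histone H1fnt, Satl1 and Sppl2c had 0 counts in both knockout libraries and were at least 439-fold, 360.0-fold, 286-fold, 263-fold, 188-fold and 177-fold lower. Smcp had 2 counts, a ratio of 1232 (95% counting interval 341 to 10177). The genes that rose most are known mainly from the epididymis, the duct next to the testis: Crisp1 measured 35.3 ± 14.5 CPM (SD) in knockout testis (log2 8.71 ± 0.52), Adam7 rose by 6.84 ± 0.36 and Serpina16 by 6.11 ± 0.56. Serpina1f, Wfdc16 and Defb28 had 1, 1 and 3 counts in wild type, with ratios of 708 (127 to 27987), 315 (56.2 to 12492) and 103 (34.8 to 501). Of 17746 genes tested 83 rose and 610 fell (edgeR quasi-likelihood, Benjamini-Hochberg), of which 80 and 602 changed by a log2 size of at least 1. Without wild-type library 1, 55 genes rose, and without knockout library 1, 200 rose. Without knockout library 2, 182 rose and 1666 fell. Grouped by column heading 342 fell. Grouped by file record, with the library headed Sox30 wild type 3 among the knockouts, edgeR called 0 genes, with 1202 at an unadjusted p under 0.05. The Sox30 level of that library, 72.8 CPM, lay nearer to the wild-type than to the knockout libraries.

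A panel of 14 epididymal genes, chosen after the values had been seen, summed to 138 and 234 CPM in the Sox30 knockout libraries and to 5.72 and 6.84 CPM in the wild-type libraries of that set. The same panel summed to 134 CPM in the wild-type library of the TGdel set, to 65.0 and 4.88 CPM in the TGdel libraries, and to values from 11.1 to 30.5 CPM in the Nkapl set.

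**Figure D2:**
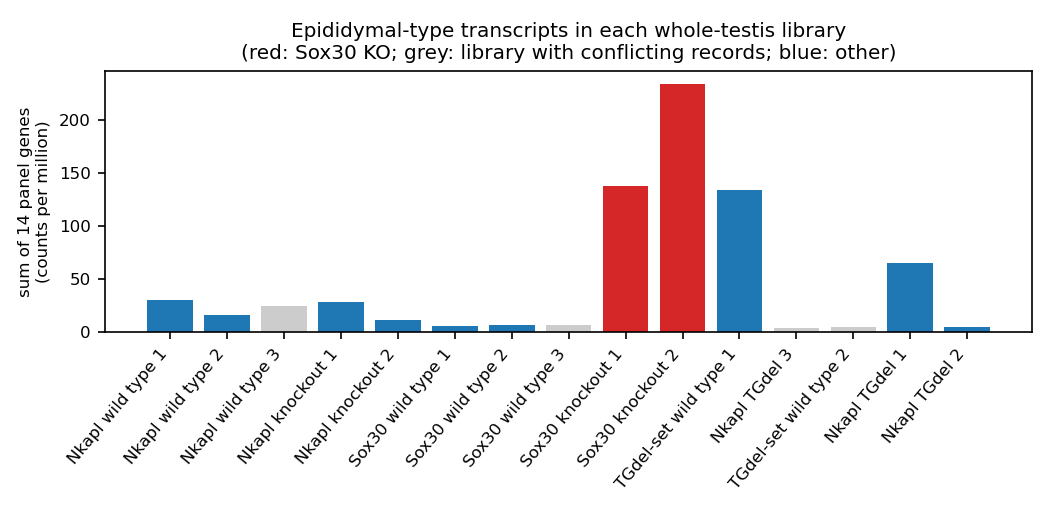
Summed CPM of 14 epididymal genes in each whole-testis library. The Sox30 knockout libraries stand at 138 and 234 CPM, and the wild-type library of the TGdel set stands at 134 CPM.

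In Sox30 knockout testis, acrosome genes fell in 19 of 37 cases (24 adjusted over the list alone, median -3.31, adjusted p = 5.75e-28, and 0.663 with an estimated correlation), including the nuclear envelope gene Sun5 (-8.44 ± 0.50). Protamine and spermatid chromatin genes fell in 10 of 21 cases (13 adjusted over the list alone, adjusted p = 1.3e-08, and 0.663 with an estimated correlation), with Hils1 at -9.34 ± 0.63 and Chd5 at -2.88 ± 0.26. Genes for sperm ion transport fell in 7 of 23 cases and rose in 1 (9 and 1 adjusted over the list alone, adjusted p = 1.3e-08, and 0.663 with an estimated correlation), with Catsper1 at -7.79 ± 0.47 and the adenylyl cyclase Adcy10 at -4.06 ± 0.28. Kinases and phosphatases fell in 4 of 24 cases (7 adjusted over the list alone, adjusted p = 4e-07, and 0.663 with an estimated correlation), with Tssk3 at -5.06 ± 0.34 and Tssk5 at -5.21 ± 0.37. Sperm tail genes fell in 8 of 51 cases, the same adjusted over the list alone (adjusted p = 1.37e-08, and 0.727 with an estimated correlation), including Ropn1 with 3 counts, a ratio of 539 (184 to 2619), and this list missed the threshold without knockout library 1 (adjusted p = 0.353). Glycolysis genes fell in 2 of 20 cases (3 adjusted over the list alone, adjusted p = 0.00457, and 0.727 with an estimated correlation), namely Gapdhs (-6.92 ± 0.41) and Hk1 (-1.20 ± 0.24). That list missed the threshold without knockout library 1 or wild-type library 2 (adjusted p = 0.252 and 0.0896), and Hk1 was not called without wild-type library 2 (-0.94). Of 2793 spermatid-enriched genes 21.3% fell and 11 genes rose (796 and 22 genes adjusted over the list alone, adjusted p = 4.67e-30, and 0.663 with an estimated correlation).

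Smaller shifts were seen in other lists in Sox30 knockout testis. The list of p53 target and apoptosis genes ranked higher (adjusted p = 0.00208, and 0.663 with an estimated correlation), but its only called member was Trp63 (1.89 ± 0.24), a p53 relative known from basal cells of epithelia, and it missed the threshold without knockout library 1 (adjusted p = 0.204). Cdh1, an epithelial adhesion gene, rose by 1.5 ± 0.31 and was not called without wild-type library 2 (1.25). Leydig cell markers ranked lower (adjusted p = 0.00282, and 0.663 with an estimated correlation) with 1 called member, Cyp17a1 (-1.56 ± 0.32), which was not called without wild-type library 1 (-0.91). The Leydig list missed the threshold without wild-type library 1 or knockout library 2 (adjusted p = 0.0918 and 0.133). Peritubular myoid markers ranked higher with 0 of 13 members called (adjusted p = 0.0285, and 0.663 with an estimated correlation), and missed the threshold without wild-type library 2 or knockout library 2 (adjusted p = 0.361 and 0.14). Spermatocyte-enriched genes ranked higher, with 3 of 2860 called higher and 1 lower (adjusted p = 0.000838, and 0.727 with an estimated correlation). They missed the threshold without knockout library 1 or wild-type library 2. Among meiotic prophase genes Rec8, which encodes a meiotic cohesin, fell by 1.20 ± 0.19. The copies Cypt2 and Cypt3 were lower, with Cypt2 at 0 counts (at least 127-fold) and Cypt3 at -6.75 ± 0.63, but reads of Cypt genes may be shared among copies.

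The TGdel comparison asks whether a second Nkapl allele changes the same transcripts. It sets 2 libraries against 1 wild-type library, which is assumed to vary like the TGdel libraries. A panel of 14 epididymal transcripts sums to 134 CPM in that library, 65.0 CPM in TGdel 1 and 4.88 CPM in TGdel 2. The actin-like genes Actl11 (log2 -4.87 ± 0.76) and Actrt2 (-4.63 ± 0.78), the sperm sodium pump Atp1a4 (-4.20 ± 0.49), Adam24 (-4.09 ± 0.52), Spert (-3.96 ± 0.82) and Scp2d1 (-3.86 ± 0.70) fell most. In the fit of all testis libraries none of these 6 genes was called without TGdel 1, with Actl11 at -3.91, Actrt2 at -3.67, Adam24 at -3.39, Atp1a4 at -3.56, Spert at -2.99 and Scp2d1 at -2.99. Without TGdel 2 only Atp1a4 was called, but the falls of the others were larger there, such as Adam24 at -5.49 and Scp2d1 at -6.5. The TGdel libraries differed widely in such genes; Atp1a4 was 0.688 ± 0.549 CPM (SD) in them and 12.9 CPM in wild type. The rises were led by the tumour suppressor Rassf1 (0.89 ± 0.12), Kri1 (0.75 ± 0.13), Trim69 (0.67 ± 0.12), Cdkl4 (0.63 ± 0.13), Ccdc77 (0.61 ± 0.12) and the topoisomerase Top3a (0.61 ± 0.13). Of 16214 genes tested 8 rose and 320 fell (edgeR quasi-likelihood, Benjamini-Hochberg), of which 1 and 242 changed by a log2 size of at least 1. In a fit of all 11 testis libraries 0 genes passed in edgeR, with 2349 at an unadjusted p under 0.05, and only this fit allows a TGdel library to be left out. It then gave 0 higher and 1 lower without TGdel 1, and 4 higher and 57 lower without TGdel 2. In a fit of this set DESeq2 called 6 higher and 136 lower, voom 18 and 631, and edgeR on thinned libraries 3 and 142 or without the filter 2 and 113. With the wild-type libraries of the Nkapl set as control, 4642 genes rose and 4632 fell. That contrast mixes the allele with the set. Rn45s took 3.96% and 3.97% of counts in Nkapl-set wild type and 0.0689% in TGdel-set wild type, and Sox30 measured 100.1 and 94.5 CPM against 54.4 CPM. Grouped by file record, edgeR called 0 genes, with 187 at an unadjusted p under 0.05.

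In TGdel testis, acrosome genes fell in 11 of 37 cases (29 adjusted over the list alone, median -1.97, adjusted p = 6.14e-30, and 0.648 with an estimated correlation), including the hyaluronidase Spam1 (-3.04 ± 0.49) and Spaca3 (-2.93 ± 0.49). Sperm tail genes fell in 7 of 51 cases (19 adjusted over the list alone, adjusted p = 1.04e-13, and 0.648 with an estimated correlation), including Iqub (-1.20 ± 0.12) and Tekt4 (-1.01 ± 0.12). Protamine and spermatid chromatin genes fell in 1 of 16 cases, Chd5 (-1.74 ± 0.22), or in 8 adjusted over the list alone (adjusted p = 2.41e-06, and 0.648 with an estimated correlation). Genes for sperm ion transport fell in 5 of 23 cases (8 adjusted over the list alone, adjusted p = 4.13e-06, and 0.648 with an estimated correlation), including Efcab9 (-2.14 ± 0.38). Glycolysis genes fell in 4 of 20 cases (8 adjusted over the list alone, adjusted p = 4.94e-06, and 0.648 with an estimated correlation), including Hk1 (-1.05 ± 0.18) and the sperm aldolase Aldoart1 (-3.12 ± 0.55). Kinases and phosphatases fell in 4 of 23 cases (6 adjusted over the list alone, adjusted p = 0.00123, and 0.648 with an estimated correlation), including Tssk2 (-2.89 ± 0.59). Pgk2 (-0.67 ± 0.12), a member of both the glycolysis and the pachytene list, fell too. Outside the lists above, Plk1 (-0.78 ± 0.12), Rec8 (-0.76 ± 0.15), Zmynd15 (-0.98 ± 0.12) and Rfx1 (-1.08 ± 0.18) fell. Of the genes named for TGdel, Atp1a4, Elfn1 and Top3a passed in the fit of all 11 testis libraries without TGdel 2, and no named gene passed in it without TGdel 1. The falls themselves remained in that fit. Without TGdel 1 and without TGdel 2, Iqub was at -1.09 and -1.25, Tekt4 at -0.96 and -1.01 and Zmynd15 at -0.89 and -1.02. Spam1 was at -2.44 and -4.02 and Tssk2 at -2.13 and -4.55.

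Spermatid-enriched genes fell in 225 of 2263 cases in TGdel testis and rose in 0 (562 and 1 adjusted over the list alone, adjusted p = 6.14e-30, and 0.648 with an estimated correlation). Spermatocyte-enriched genes ranked higher with 4 of 2851 called (adjusted p = 8.21e-10, and 0.648 with an estimated correlation). The R-loop and transcription-replication list also ranked higher (adjusted p = 0.0213, and 0.648 with an estimated correlation), with 0 of 27 members called. Endothelial (adjusted p = 0.025, and 0.835 with an estimated correlation) and macrophage markers (adjusted p = 0.0365, and 0.648 with an estimated correlation) ranked higher with 0 members called, and missed the threshold without TGdel 2 (adjusted p = 0.4 and 0.498). The share of Rn45s was 0.0689% in the wild-type library and 0.497% and 0.0666% in the TGdel libraries.

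The testis comparisons share no libraries, so their calls can be set side by side. Fisher's exact test takes genes as independent, which they are not. The estimated correlation between spermatid-enriched genes was 0.14 in Nkapl knockout and 0.183 in Sox30 knockout testis. The p-values of the overlaps are therefore too small, and the counts shared and expected are the values to read. Of 471 genes lower in Sox30 knockout testis and tested in both, 459 were also lower in Nkapl knockout testis, where 108.5 were expected for independent calls (one-sided Fisher's exact test, p = 6.91e-281). They include Tex36, the transporter Slc22a14, Prr30 and the piRNA factor relative Gtsf1l, with log2 fold changes of -6.67, -5.55, -7.43 and -6.30 in Nkapl knockout testis. In Sox30 knockout testis Slc22a14 and Gtsf1l were at -7.20 and -9.11, Tex36 had 2 counts (ratio 826, 228 to 6828) and Prr30 had 1 (ratio 2009.9, 360.3 to 79425). No gene was higher in both by DESeq2 or by edgeR in the main fits, with 5.8 expected for the calls of edgeR (Fisher's exact test, p = 1). With the replicate number as a block edgeR gave 40, with 29.5 expected (one-sided Fisher's exact test, p = 0.0267), and the fit of all testis libraries gave 1. Without Sox30 knockout library 2, 1338 genes were lower in both and 50 higher in both. Of 318 genes lower in TGdel testis 310 were also lower in Nkapl knockout testis, with 73.7 expected (Fisher's exact test, p = 1.29e-187). The fatty acid hydroxylase Fa2h fell by 2.73 in Nkapl knockout and by 1.72 in TGdel testis, Tsnaxip1 fell by 0.97 and 1.39, Ccdc38 fell by 1.46 and 1.39, Elfn1 fell by 3.26 and 2.47, and the kinase Pik3cd fell by 1.60 and 1.39. Rassf1, Kri1, Top3a and Ccdc77 were the 4 genes higher in both, of 8 higher in TGdel (1.0 expected, Fisher's exact test, p = 0.0133), and Ccdc77 was not called in Nkapl knockout testis without wild-type library 1 (0.16) or knockout library 2 (0.19). The TGdel calls rest on 1 wild-type library, and in the fit of all testis libraries edgeR called 0 genes in TGdel, with 2349 at an unadjusted p under 0.05, so 0 were shared. Without TGdel 1, in that fit, 1 gene was lower in both and 0 were higher in both. Without TGdel 2, 42 were lower in both. Across genes, which are not independent replicates, log2 fold changes of Nkapl knockout testis correlated at r = 0.68 with Sox30 knockout and r = 0.76 with TGdel, and those of Sox30 knockout at r = 0.51 with TGdel.

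Tests of the difference between effects asked where the alleles part. The effect of the Nkapl knockout was higher than that of the Sox30 knockout for 4 genes and lower for 141 (edgeR quasi-likelihood, Benjamini-Hochberg). Tnfaip2 fell more in Sox30 knockout (log2 -2.69 ± 0.18) than in Nkapl knockout testis (-0.35 ± 0.09), a difference of 2.37 ± 0.18 (adjusted p = 0.00434). The synaptic vesicle gene Svop, the prekallikrein gene Klkb1 and the imprint regulator Zfp57 fell in Nkapl knockout (-0.86, -2.88 and -1.69) and rose in Sox30 knockout testis (1.69, 2.66 and 1.54). Their differences were -2.53 ± 0.22, -5.53 ± 0.49 and -3.21 ± 0.28 (adjusted p = 0.00434 each). The epididymal panel summed to 138 and 234 CPM in the Sox30 knockout libraries, against 5.72 and 6.84 CPM in their wild type. Whether these rises share the source of those transcripts was not tested. The knockouts also lie in sets that differ in depth and in spread between libraries. Ccdc81 fell in Nkapl knockout (-5.56 ± 0.17) and did not pass in Sox30 knockout testis (1.13 ± 0.32, adjusted p = 0.176), a difference of -6.67 ± 0.55 (adjusted p = 0.00434). Sperm tail genes ranked lower in the Nkapl effect (median -0.40, adjusted p = 2.64e-06, and 0.875 with an estimated correlation). Glycolysis genes also ranked lower (2 of 20 lower, also adjusted over the list alone, adjusted p = 0.0217). Sertoli cell markers (median 0.26, 0 of 23 called, adjusted p = 0.000348) and spermatocyte-enriched genes (median 0.09, 0 of 2861 higher and 2 lower, adjusted p = 6.95e-07) ranked higher. With an estimated correlation each of these had an adjusted p of 0.875. Without Sox30 knockout 2 all 4 lists missed the threshold (sperm tail 0.35, glycolysis 0.367, Sertoli 0.316, spermatocyte-enriched 0.202). Without Sox30 wild type 1 the sperm tail (0.0623), glycolysis (0.215) and Sertoli lists (0.161) did. Without Sox30 knockout 1, 1373 genes differed, and without any other single library except Sox30 knockout 2 (241 genes) between 8 and 36 did. DESeq2 called 513 genes and voom 5.

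Between the Nkapl alleles, the effect of the knockout was lower than that of TGdel for 119 genes and higher for 4. Fer1l5 fell by 4.35 ± 0.10 in knockout and by 1.98 ± 0.27 in TGdel testis (difference -2.39 ± 0.23, adjusted p = 0.02). Tex21 fell by 4.85 and 1.69 (difference -3.18 ± 0.34, adjusted p = 0.0289) and Zan fell by 5.89 and 2.28 (difference -3.64 ± 0.43, adjusted p = 0.0353). The calcium channel gene Cacna1h (-1.38 and -0.50) and the secreted kinase relative Fam20a (-1.75 and 0.26) did not pass in TGdel testis, and their differences were -0.90 ± 0.11 and -2.03 ± 0.26 (adjusted p = 0.0353 each). Acrosome genes ranked lower in the knockout effect (median difference -2.09; 30 of 37 lower adjusted over the list alone, 0 over all genes, adjusted p = 9.3e-10, and 0.32 with an estimated correlation), as did sperm tail genes (30 of 51 adjusted over the list alone, 4 over all genes, adjusted p = 8.61e-15, and 0.32 with an estimated correlation). Spermatocyte-enriched genes ranked higher in this test although their median (-0.01) and mean (-0.02) were below 0 (adjusted p = 0.000889, and 0.33 with an estimated correlation). They missed the threshold without TGdel 2 (adjusted p = 0.0928). Markers of Sertoli cells (adjusted p = 8.26e-07), peritubular myoid cells (0.000797), differentiating (0.000643) and undifferentiated spermatogonia (0.0083) and Notch pathway genes (0.0132) also ranked higher. Pachytene genes (9.51e-08, and 0.297 with an estimated correlation), ion transport genes (6.26e-07), glycolysis genes (0.000106), spermatid transcription regulators (0.000106), kinases and phosphatases (0.00024) and spermatid-enriched genes (0.000471, and 0.537 with an estimated correlation) ranked lower. The others of these lists had 0.32 with an estimated correlation. Without TGdel 1 the Notch (0.13) and myoid lists (0.0831) missed the threshold, and without TGdel 2 the spermatid-enriched list did (0.152). The calls of these differences depend on single libraries, while the sizes of the 5 named genes moved little. Without 1 library of the Nkapl set, Fer1l5 lay between -2.4 and -2.22, Tex21 between -3.38 and -2.93 and Zan between -3.8 and -3.45. Cacna1h lay between -0.92 and -0.69 and Fam20a between -2.07 and -1.81. Without wild-type 1, wild-type 2, knockout 1 or knockout 2 of the Nkapl set, edgeR called 0 genes, with 2167, 2130, 2120 and 1734 at an unadjusted p under 0.05, and without TGdel 1 or TGdel 2 it called 2137 and 1450. With all libraries, DESeq2 called 400 and voom 86.

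In sorted pachytene spermatocytes the question is which transcripts differ before the haploid phase. For spermatid transcripts the fraction cannot answer it, because spermatid RNA carried into the fraction is not excluded. Over 13 late spermatid genes, the change in spermatocytes minus that in spermatids lay between -0.05 and 0.67 (log2). The sample titles do not say whether the 2 libraries of a sorted group come from separate mice. Their biological coefficient of variation was 3.7%. If they share mice, p-values and counts of calls in sorted cells do not cover the spread between mice. The directions here rest on the labels. Nkapl was higher in the libraries labelled knockout, but this transcript does not settle the genotype, as the removed part is not stated. Knockout testis also kept 60.9 CPM of Nkapl, against 75.8 CPM in wild-type testis of that set. Other values ran the way of the labels. Log2 fold changes correlated across genes at r = 0.75 with those in knockout spermatids. Reads assigned to no counted feature made up 17.3% against 13.6% in wild type, and in spermatids 18.2% against 13.6%. In the libraries labelled knockout (n = 2) the protamine gene Prm1, which packs sperm DNA, was 31.6 ± 3.46 CPM (SD) against 304 ± 13.4 CPM in the libraries labelled wild type (n = 2), a log2 change of -3.20 ± 0.06 (adjusted p = 2.97e-25). The transition protein gene Tnp2 fell by 2.56 ± 0.05. The glutamate receptor gene Grin2b had 0 counts and was at least 33.9-fold lower, and Lexm (-4.27 ± 0.24), Tex46 (-4.27 ± 0.41), Spatc1 (-3.90 ± 0.12) and Filip1 (-3.84 ± 0.36) fell strongly. Hmgb1-rs17 also fell (-4.24 ± 0.27), with reads that a paralog may share. The death receptor gene Tnfrsf21 (2.75 ± 0.21), Erich5 (2.21 ± 0.29), Lmln (2.13 ± 0.10), Espnl (2.08 ± 0.21), Cd74 (2.03 ± 0.42) and the protocadherin Pcdha3 (2.01 ± 0.31) rose most. Of 15805 genes tested 5304 rose and 4059 fell (edgeR quasi-likelihood, Benjamini-Hochberg), of which 451 and 1271 changed by a log2 size of at least 1. A fit of only the 4 libraries compared gave 4057 higher and 4388 lower, so the majority direction is not fixed.

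Genes of the piRNA pathway, which silences transposons in germ cells, rose in 21 of 26 cases in the spermatocyte libraries labelled knockout and fell in 1 (22 and 1 adjusted over the list alone, median 0.44, adjusted p = 1.39e-06, and 0.175 with an estimated correlation), including Pld6 (0.98 ± 0.05) and Tdrd5 (0.79 ± 0.05). The R-loop and transcription-replication list rose in 18 of 27 cases and fell in 0, the same adjusted over the list alone (adjusted p = 0.000335, and 0.226 with an estimated correlation), including the helicase Dhx9 (0.92 ± 0.06). Pachytene genes rose in 19 of 29 cases and fell in 5, the same adjusted over the list alone (adjusted p = 0.00576, and 0.131 with an estimated correlation), with Cks2 at 0.69 ± 0.06 and the phosphatase Cdc25c at -1.73 ± 0.10. Protamine and spermatid chromatin genes fell in 14 of 21 cases and rose in 3 (adjusted p = 2.39e-08, and 0.104 with an estimated correlation), and acrosome genes fell in 27 of 37 cases and rose in 4 (adjusted p = 3.47e-09, and 0.104 with an estimated correlation), each the same adjusted over the list alone, with Sppl2c at -1.44 ± 0.06. Glycolysis genes fell in 12 of 20 cases and rose in 5 (adjusted p = 0.00602, and 0.131 with an estimated correlation), and sperm tail genes fell in 24 of 51 cases and rose in 12 (adjusted p = 0.00571, and 0.175 with an estimated correlation), again the same adjusted over the list alone. Gpi1 (-1.22 ± 0.06), Pkm (-1.11 ± 0.06), Ttc21a (-0.92 ± 0.05) and Odf1 (-0.78 ± 0.05) were their called members with the smallest p. Falls in the protamine, acrosome and sperm tail lists may come from spermatid RNA in this fraction. Sertoli cell markers fell in 15 of 23 cases, the same adjusted over the list alone (adjusted p = 0.000251, and 0.118 with an estimated correlation), including Espn (-1.0 ± 0.10) and Clu (-0.54 ± 0.05). The list of transcription elongation and pausing factors did not pass (20 of 39 rose and 8 fell, adjusted p = 0.0754), with Supt6 at 0.70 ± 0.05 and Ell2 at -0.88 ± 0.07.

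In knockout round spermatids, Nkapl goes with the labels (n = 2 libraries against 2). Prm1 fell from 1079.8 ± 39.4 CPM (SD) to 72.9 ± 2.69 CPM, a log2 change of -3.86 ± 0.06 (adjusted p = 2.36e-28), and Tnp2 fell from 1530.7 ± 33.4 to 161 ± 7.30 CPM (-3.22 ± 0.05). The carbonic anhydrase Car2 (-4.88 ± 0.13), Odf3b (-4.79 ± 0.25), Filip1 (-4.72 ± 0.25), Grin2b (-4.60 ± 0.27) and the Wnt ligand gene Wnt3 (-4.46 ± 0.18) fell most, beside Hmgb1-rs17 (-4.56 ± 0.18). Tnfrsf21 (3.83 ± 0.20), the receptor Gpr179 (3.08 ± 0.13), Slc4a3 (3.05 ± 0.40), the T-box gene Tbx4 (2.90 ± 0.27), Erich5 (2.70 ± 0.20) and Zhx2 (2.63 ± 0.22) rose most. Of 15805 genes tested 4582 rose and 4903 fell (edgeR quasi-likelihood, Benjamini-Hochberg), of which 1113 and 1542 changed by a log2 size of at least 1. With the size factors of DESeq2 the majority turned, to 4862 higher and 4686 lower.

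Protamine and spermatid chromatin genes fell in 16 of 21 cases in knockout round spermatids and rose in 1, the same adjusted over the list alone (median -0.87, adjusted p = 3.04e-09, and 0.136 with an estimated correlation). Sperm tail genes fell in 37 of 51 cases and rose in 3 (38 and 3 adjusted over the list alone, adjusted p = 1.56e-07, and 0.136 with an estimated correlation), including Ttc21a (-1.11 ± 0.05) and Oaz3 (-0.97 ± 0.05). Acrosome genes fell in 27 of 37 cases and rose in 4 (28 and 4 adjusted over the list alone, adjusted p = 4.71e-05, and 0.141 with an estimated correlation), with Sppl2c at -1.76 ± 0.05. Kinases and phosphatases fell in 14 of 24 cases and rose in 4, the same adjusted over the list alone (adjusted p = 0.00975, and 0.141 with an estimated correlation), including Tssk6, needed for chromatin packing in spermatids (-2.02 ± 0.08), and Camk4 (-1.77 ± 0.08). Glycolysis genes fell in 12 of 20 cases and rose in 5 (13 and 5 adjusted over the list alone, adjusted p = 0.0209, and 0.167 with an estimated correlation), with Gpi1 at -2.04 ± 0.06 and Pkm at -1.49 ± 0.06.

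Genes of the piRNA pathway rose in 18 of 26 cases in knockout round spermatids and fell in 2 (18 and 3 adjusted over the list alone, adjusted p = 0.000648, and 0.29 with an estimated correlation), including Pld6 (0.78 ± 0.07) and Tdrd1 (0.68 ± 0.07). The R-loop list rose in 13 of 27 cases and fell in 3, the same adjusted over the list alone (adjusted p = 0.0209, and 0.405 with an estimated correlation), including Brca1 (0.72 ± 0.07). Macrophage markers rose in 14 of 16 cases and fell in 1, the same adjusted over the list alone (median 1.33, adjusted p = 0.00135, and 0.136 with an estimated correlation), at low levels such as 12.4 ± 0.720 CPM for Lyz2 (1.60 ± 0.15), with Cd74 at 1.94 ± 0.20. Leydig cell markers rose in 10 of 14 cases and fell in 1 (11 and 1 adjusted over the list alone, median 1.5, adjusted p = 0.0163, and 0.202 with an estimated correlation), with Cyp17a1 at 1.28 ± 0.16 and Scarb1 at -2.20 ± 0.08. Meiotic division genes rose in 16 of 34 cases and fell in 8 (17 and 8 adjusted over the list alone, adjusted p = 0.0341, and 0.278 with an estimated correlation), including Cdc20 (0.64 ± 0.05). Pachytene genes rose in 13 of 29 cases and fell in 6, the same adjusted over the list alone (adjusted p = 0.0341, and 0.175 with an estimated correlation), including the cohesin guard Sgo2a (0.86 ± 0.07). Meiotic division genes missed the threshold without wild-type spermatids 2 or knockout spermatids 2 (adjusted p = 0.0512 and 0.0537). Pachytene genes missed it without wild-type spermatids 2, knockout spermatids 1 or knockout spermatids 2 (adjusted p = 0.0642, 0.0699 and 0.0545).

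**Figure D3:**
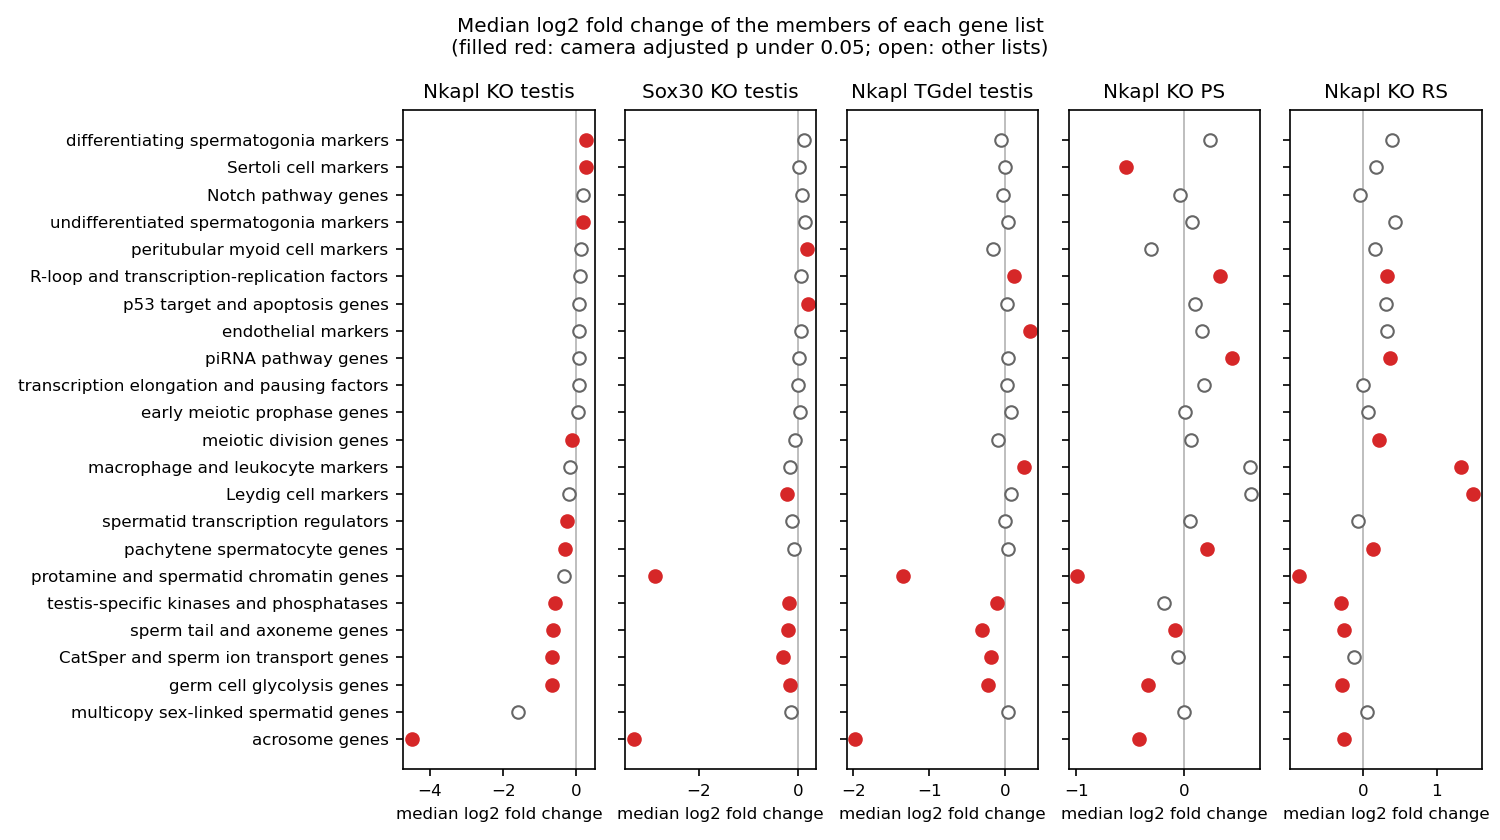
Median log2 fold change of each gene list in the testis and sorted-cell comparisons, 1 panel per comparison. The x axes differ between panels; acrosome genes stand at -4.50 in Nkapl knockout testis, at -0.42 in spermatocytes labelled knockout and at -0.26 in knockout round spermatids.

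Wild-type round spermatids against wild-type pachytene spermatocytes show which transcripts mark each fraction (n = 2 libraries against 2). The spermatocyte libraries are wild type by labels that their Nkapl level runs against without settling them, and exchanged labels would change these values. Tnp2 (log2 1.88 ± 0.05), Tnp1 (1.83 ± 0.05), Akap4 (1.62 ± 0.05) and Akap3 (1.49 ± 0.04) were higher in spermatids, and so was Sox30 (1.0 ± 0.06). The piRNA pathway genes Piwil1 (-3.59 ± 0.06) and Tdrd5 (-3.81 ± 0.07) and the synaptonemal complex gene Sycp3 (-1.63 ± 0.06) were lower. The largest rises were in Csf1r (3.35 ± 0.32), Cd74 (2.73 ± 0.38), Olfr19 (2.42 ± 0.28), Lyz2 (2.33 ± 0.26), Car2 (2.14 ± 0.09) and the copy gene Cypt15 (2.1 ± 0.18), and the largest falls in Zfp389 (-4.63 ± 0.17), the gap junction gene Gja1 (-4.17 ± 0.25), Enpp2 (-4.14 ± 0.29), Pou5f2 (-4.12 ± 0.09), Hepacam2 (-4.12 ± 0.22) and Ccdc142 (-4.07 ± 0.14). Of 15805 genes 6494 were higher and 5751 lower (edgeR quasi-likelihood, Benjamini-Hochberg), of which 3167 and 2866 differed by a log2 size of at least 1, and a fit of only the 4 libraries gave 5752 and 6137. Acrosome genes were higher in 36 of 37 cases (36 adjusted over the list alone, median 1.37, adjusted p = 4.47e-13, and 0.0649 with an estimated correlation). Sertoli cell markers were lower in spermatids in 22 of 23 cases (22 adjusted over the list alone, median -2.15, adjusted p = 6.77e-07, and 0.0649 with an estimated correlation), led by Clu (-3.32 ± 0.07) and Ctsl (-2.55 ± 0.09). The piRNA list was lower in 17 of 26 cases and higher in 7, the same adjusted over the list alone (adjusted p = 0.000259, and 0.221 with an estimated correlation).

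The effects in the sorted fractions, by their labels, were compared as the effect in spermatids minus the effect in spermatocytes. Nkapl differed most clearly (-2.40 ± 0.09, adjusted p = 4.93e-18), since it was lower in knockout spermatids and higher in the spermatocyte libraries labelled knockout. The secretory coat gene Sec23a went the same ways, at 0.51 ± 0.07 in spermatocytes and -2.40 ± 0.09 in spermatids (difference -2.92 ± 0.12, adjusted p = 3.74e-17). Herpud1, a gene of protein quality control, was 0.19 ± 0.06 and -1.80 ± 0.07 (difference -1.99 ± 0.09, adjusted p = 1.32e-15). Rbm28 (-1.91 ± 0.08) and the Ran exchange factor Rcc1 (-1.19 ± 0.06) fell in spermatids, with differences of -1.81 ± 0.10 and -1.24 ± 0.08 (adjusted p = 3.22e-13 and 3.86e-12). The effect was higher in spermatids for 1426 genes and lower for 2599 (edgeR quasi-likelihood, Benjamini-Hochberg), and with the size factors of DESeq2 this split became 1941 and 1902. DESeq2 called 2194 genes in all, against 4025. Without knockout spermatids 1, 2679 differed. Sertoli cell markers ranked higher in the spermatid effect (11 of 23 higher and 0 lower, 12 and 0 adjusted over the list alone, adjusted p = 6.73e-06, and 0.138 with an estimated correlation), and elongation and pausing factors ranked lower (0 of 39 higher and 19 lower, 0 and 20 adjusted over the list alone, adjusted p = 0.00115, and 0.138 with an estimated correlation). Acrosome genes (12 of 37 higher and 2 lower, adjusted p = 0.000388, and 0.203 with an estimated correlation), Leydig cell markers (5 of 14 higher and 1 lower, 0.0184, and 0.257) and meiotic division genes (9 of 34 higher and 7 lower, 0.0272, and 0.272) also ranked higher. Sperm tail genes (3 of 51 higher and 24 lower, 0.000728, and 0.203) and protamine and spermatid chromatin genes (0 of 21 higher and 8 lower, 0.0217, and 0.266) ranked lower. Without wild-type spermatids 1 the Leydig and protamine lists missed the threshold (0.063 and 0.0622), and without wild-type spermatids 2 the Leydig list did (0.0829). Log2 fold changes of the fractions, which share 1 fit but no libraries, correlated across genes at r = 0.75, and those of Nkapl knockout testis correlated at r = 0.14 with spermatids and r = 0.26 with spermatocytes.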

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

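The tests of differences between effects were planned, and every test of an explanation in these paragraphs was chosen after the result it concerns had been seen.

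Epididymal transcripts were higher in both Sox30 knockout testis libraries, where a panel of 14 genes summed to 138 and 234 CPM and Crisp1 alone to 25.8 and 44.7 CPM, and epididymal tissue in the dissected samples is 1 hypothesis for their source. Under it libraries with Sox30 intact should carry the panel too, and sorted cells should not (6.56 to 20.9 CPM, mostly Ces5a and Cuzd1, which germ cells express themselves). In a first test with a bound of 68.4 CPM, 1 library outside the knockouts exceeded it (the wild-type library of the TGdel set, at 134 CPM, where at least 2 were required), and TGdel 1 stood just below, at 65.0 CPM. A second test, added once the first had missed its bound, found 6 libraries, among them Nkapl wild type 3, which was left out of the comparisons but is no Sox30 knockout by record or heading, whose profile over the panel genes correlated at 0.9 or more with the knockout mean, so the hypothesis stays open, with tests that differ. Loss of Sox30 as the only source is argued against by 6 libraries with Sox30 intact whose panel sums passed the bound for it, and still by 5 without Ces5a and Cuzd1. Both counts include Nkapl wild type 3 (24.1 CPM, and 12.5 CPM without Ces5a and Cuzd1). Among the 5 are also wild type of the TGdel set (89.0 CPM) and TGdel 1 (44.4 CPM), against 80.9 CPM in the lower knockout and at most 1.49 CPM in sorted cells. A contribution of the knockout stays open.

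Late spermatid transcripts such as Prm1 and Tnp2 were lower in the pachytene spermatocyte libraries labelled knockout. Their Nkapl level goes against these labels without settling them. Transcription of these genes in spermatocytes would give ratios of wild-type spermatocytes to spermatids that differ between genes, and the SD of the ratio over 13 late genes was 0.15 (log2) by the labels, around a median of -1.63, and 1.17 with the spermatocyte labels exchanged. Spermatid RNA carried into the spermatocyte fraction would keep their changes in both fractions alike, and the SD of the difference between these changes was 0.26 by the labels, between the bound for this explanation (0.25) and the bound against it (0.5), and 2.31 with the labels exchanged. By the labels, the SD of 0.15 lies under 0.25, the bound set against transcription in spermatocytes. It argues against such transcription as the main source for these 13 genes, but only if the labels hold. Log2 fold changes by the labels correlated across genes at r = 0.75 with those in knockout spermatids, and exchanged labels would turn that sign. Relative to sorted wild-type spermatids, the late transcripts had a median of -6.13 (log2) in wild-type testis, which holds spermatocytes, and -1.63 in wild-type spermatocytes. This also argues against transcription in spermatocytes as the main source, if the sorted cells match those in testis. For Prm1 the values were -13.23 and -1.89, a gap wider than its change of -3.20 between the spermatocyte groups, so exchanged labels would not close it. Carry-over of spermatid RNA stays open. The fractions were sorted, and no label gives their purity.

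Of 21 spermatid transcripts tested in both, all but Tssk6 (-0.86 in testis and -2.02 in sorted spermatids) fell more in Nkapl knockout testis than in sorted knockout spermatids, Tnp1 by little (-3.77 and -3.06). The changes in knockout testis were not alike, with an SD of 2.71 (log2) over these genes. It was 1.97 over 14 genes above 3 counts in knockout testis and over 2-fold lower in wild-type spermatocytes, which ranged from -7.41 to -0.86. A loss of spermatids that lowers all their transcripts alike still stays open. A gene over 2-fold lower in spermatocytes may be expressed there in part, and that part need not fall with spermatids. Spermatid RNA in the spermatocyte fraction, which is not excluded, would hide how large this part is. Sorted spermatids from a later step than those in the testis samples are a candidate explanation, since wild-type testis held less of late than of early transcripts relative to sorted spermatids, by a median of -2.09. That value lies close to the bound of -2 set for it. Prm1, which like Prm2 and Tnp2 was not tested in testis, measured 0.112 CPM in wild-type testis and 1079.8 CPM in sorted wild-type spermatids, and the age of the mice behind the sorted cells stands only in the sample titles.

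The effects of the Nkapl and Sox30 knockouts differed by test for 145 genes, with log2 differences of 2.37 for Tnfaip2, -6.67 for Ccdc81, -2.53 for Svop, -5.53 for Klkb1 and -3.21 for Zfp57. Whether the source of the epididymal transcripts in Sox30 knockout testis also raised Svop, Klkb1 and Zfp57 there was not tested. The effects of the Nkapl knockout and TGdel differed by test for 123 genes, with -2.39 for Fer1l5, -3.18 for Tex21, -3.64 for Zan, -0.90 for Cacna1h and -2.03 for Fam20a. The effects in round spermatids and in pachytene spermatocytes differed by test for 4025 genes. They rest on labels that the Nkapl level in spermatocytes goes against without settling them. The differences were -2.40 for Nkapl, -2.92 for Sec23a, -1.99 for Herpud1, -1.81 for Rbm28 and -1.24 for Rcc1. Reads that HTSeq assigned to no counted feature, which no comparison used, made up 17.3% ± 0.247 (SD, n = 2) in spermatocytes labelled knockout against 13.6% ± 0.921 in wild type. In spermatids they made up 18.2% ± 0.140 in knockout against 13.6% ± 0.0547 in wild type. The annotation and strand setting are not given, so reads in introns or antisense to genes may be among them.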

How the results depend on the processing

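Grouping by file record and grouping by column heading were tried only after the values had been seen, and the other alternatives were planned. Of the counts of calls recomputed under an alternative, 190 stayed within 1.5 times the reported count and 105 did not. Of the values of named genes, 5031 kept their direction and side of the threshold and 57 gained the call. In 412 the call was lost, 159 of them by file record, and 1 turned, Trim69 in TGdel testis at -0.01 by file record against 0.67. Of the list tests, 2556 kept theirs, 160 lost the call (92 of them with an estimated correlation) and 124 gained it. Where nothing else is said, the cause was not tested.

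By file record all testis comparisons had 0 calls in edgeR, the only tool run there, so higher and lower in Nkapl knockout, Sox30 knockout and TGdel, both testis differences and all overlaps were 0. At an unadjusted p under 0.05 there were 415, 1202 and 187 genes in these comparisons and 376 and 144 in the differences. In the Nkapl set the values of the library that record and heading dispute go with its heading, wild type 3. Its Rn45s share was 3.97%, against 3.96% and 3.97% in wild type and 5.53% and 5.29% in knockout. It had counts in 20094 genes, against 20082 and 20033 in wild type and 19427 and 19412 in knockout. The 0 calls by file record in that set therefore say little about the knockout. In the Sox30 set the disputed library, headed wild type 3, had an epididymal panel sum of 6.26 CPM. Wild type had 5.72 and 6.84 CPM and knockout 138 and 234 CPM. Its Sox30 level of 72.8 CPM also lay nearer to wild type (78.2 and 84.0 CPM) than to knockout (46.2 and 60.3 CPM). These values go with its heading, while its 20334 genes with counts lay between the groups. By column heading 342 genes were lower in Sox30 knockout, 32 were higher and 168 lower in TGdel, 501 and 1997 differed between Nkapl knockout and Sox30 knockout or TGdel, and 164 were lower and 14 higher in Nkapl knockout and TGdel.

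DESeq2 gave 1090 genes higher in Nkapl knockout, 136 lower in TGdel, differences of 513 (Sox30), 400 (TGdel) and 2194 (spermatids against spermatocytes) and 133 genes lower in Nkapl knockout and TGdel. Voom gave 18 higher and 631 lower in TGdel, 5 genes for the difference from Sox30, and 604 lower and 10 higher in both Nkapl alleles. DESeq2's size factors gave 4 higher in TGdel, 33 for the difference from TGdel and 2 higher in both alleles, and moved the median of all genes by at most 0.063 (log2) in size. Without the filter there were 2 higher and 113 lower in TGdel, 336 and 439 for the differences from Sox30 and TGdel, and 112 lower and 1 higher in both alleles. Thinned libraries gave 3 higher and 142 lower in TGdel and 140 lower and 2 higher in both alleles.

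The fit of all 11 testis libraries gave 195 higher and 1688 lower in Nkapl knockout, 0 and 0 in TGdel (2349 at an unadjusted p under 0.05, edgeR only), 1 gene higher in Nkapl and Sox30 knockout, and 0 lower and 0 higher in both alleles. It pools the spread of sets that differ, with a biological coefficient of variation of 4.6% in the Nkapl set, 16.6% in the Sox30 set and 12.5% in the TGdel set. With Nkapl-set wild type as control TGdel had 4642 higher and 4632 lower, with 1836 lower and 685 higher in both alleles. With both wild-type groups it had 2351 and 2698, with 1617 and 406. These overlaps share the Nkapl-set wild-type libraries between both comparisons, so their calls are not independent. With these controls the allele is also mixed with differences between the sets. With a log2 size of at least 1, 34 genes were higher and 1349 lower in Nkapl knockout, 1 was higher in TGdel, 451 and 1271 changed in spermatocytes, 1113 and 1542 in spermatids and 3167 and 2866 between wild-type fractions. The differences then held 54 (TGdel) and 603 (fractions) genes, and 0 were higher in both alleles.

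Without 1 library, a lone library is assumed to vary like the other groups. Genes higher in Nkapl knockout numbered 1210 (without knockout 2) to 2355 (without wild type 1). In Sox30 knockout 55 (without wild type 1) to 200 (without knockout 1) were higher and 491 (without wild type 2) to 1666 (without knockout 2) lower. In TGdel, where only the fit of all testis libraries allows this and that fit has 0 calls with all libraries, 0 to 4 were higher and 1 to 57 lower, the smaller values without TGdel 1 (1684 at an unadjusted p under 0.05), so the loss cannot be put down to the library left out. The difference from Sox30 held 8 genes without Nkapl-set wild type 1 and 1373 without Sox30 knockout 1. The difference from TGdel held 0 in edgeR without any 1 of the Nkapl-set libraries, with 1734 to 2167 at an unadjusted p under 0.05, and 2137 without TGdel 1. That between the fractions held 2679 (without knockout spermatids 1) to 4449 (without wild-type spermatocytes 1). Nkapl and Sox30 knockout shared 406 (without Sox30 wild type 2) to 1338 genes lower and 0 to 50 higher, both upper values without Sox30 knockout 2, and the Nkapl alleles shared 1 (without TGdel 1) to 314 lower and 0 to 4 higher.

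Same-numbered libraries have 2 pairs per comparison, and no label says what a number marks. Their deviations from group means correlated across genes at 0.03 in the Nkapl set, 0.42 in the Sox30 set and between -0.02 and 0.05 in sorted cells. Numbers were not taken as pairs, as no label makes them pairs, and in the Sox30 set the value leaves open what they share. With the replicate number as a block, Nkapl knockout had 2141 genes higher and 3837 lower, Sox30 knockout 303 and 1367, spermatocytes 5317 and 4055, spermatids 4600 and 4905 and wild-type fractions 6483 and 5758. The block gave differences of 977 (Sox30), 2358 (TGdel) and 4076 (fractions), and 1039 genes lower and 40 higher in Nkapl and Sox30 knockout. For TGdel against wild type, no paired analysis was possible because that set has 1 wild-type library.

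Small changes are hard to find in the Sox30 and TGdel sets. In simulated counts, a log2 change of 0.5 was found in 62.7% of genes in the Nkapl set, 3% in the Sox30 set and 17.9% in the TGdel set. For sorted cells it was found in 76.1% in spermatocytes labelled knockout, 49.3% in knockout spermatids and 59.7% between the wild-type fractions.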

Other observations

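The X chromosome was looked at only after the values had been seen. In knockout round spermatids the median log2 fold change was 0.34 over 603 X-linked genes and 0.02 over 14813 autosomal genes, with 245 X-linked genes higher and 81 lower (edgeR quasi-likelihood, Benjamini-Hochberg). The autosomes had 4235 higher and 4699 lower. In the spermatocyte libraries labelled knockout the X-linked median was -0.03 against 0.07 on autosomes, with 74 X-linked genes higher and 111 lower. The difference of the effects by label between the fractions had a median of 0.31 on the X and -0.04 on autosomes, with 99 X-linked genes higher in the spermatid effect and 8 lower. In wild-type cells X-linked genes were higher in spermatids than in spermatocytes by a median of 0.78, against 0.03 on autosomes, and in Nkapl knockout testis the X-linked median was 0.14 against 0.00. No explanation of these values was tested.

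Among libraries left out because their record and heading name different groups, Nkapl measured 78.4 CPM in the library headed Nkapl wild type 3, close to the 73.9 and 77.6 CPM of the other wild-type libraries of that set. Sox30 measured 72.8 CPM in the library headed Sox30 wild type 3, against 78.2 and 84.0 CPM in the wild-type and 46.2 and 60.3 CPM in the knockout libraries. In the TGdel set, Nkapl measured 105.0 CPM in the library headed wild type 2 and 123 CPM in that headed TGdel 3. The epididymal panel summed to 4.66 CPM in the former and 3.66 CPM in the latter.

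Libraries of a group differed from counting noise to unequal degrees. The ratio of observed to counting variance between replicates was 1.40 in spermatocytes labelled knockout, 1.77 and 2.45 in knockout and wild-type spermatids, 2.50 and 4.20 in knockout and wild-type testis of the Nkapl set, 4.85 in wild-type spermatocytes, 16.9 in TGdel testis, and 21.3 and 42.0 in wild-type and knockout testis of the Sox30 set.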
